A study of Drosophila melanogaster with 6 samples.

How the data were processed

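HP2 was mapped by ChIP-seq in 14 to 16 h wild-type Oregon-R embryos fixed with 1.8% formaldehyde. Of the 6 libraries, 3 were HP2 immunoprecipitations and 3 were inputs, and groups and replicate numbers were taken from the labels. Enriched-region lists of the 3 immunoprecipitation libraries and 1 combined list of the replicate set were used; per-library values of the inputs were not analysed here.

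Bowtie 0.12.7 is named in the submitters' processing notes, and the coordinates are in FlyBase release 5, per the file headers. The region caller, its threshold, its filters and the way the replicates were combined are not given in the sources used here. Per the labels, each replicate list was called against the input of that replicate. The authors deposited a score for each region, and neither its scale nor its log base is stated per the file headers. The scale was therefore read from the values. In each list, the differences between the commonest score and the next 29 commonest scores were compared with the logarithms of ratios of whole numbers up to 12, with a tolerance of 1e-06. Between 9 and 16 of the 29 matched in base 2, and at most 1 in base e or base 10. The scores were taken as log2 values of count ratios with an unknown constant per list, and were ranked or compared only within a list. Starts and ends were all even in the combined list and about evenly split in the replicate lists, so the lists were made on different grids. The shortest region was 1301 bp in each replicate list and 1001 bp in the combined list, a limit that affects which short regions can be shared. Region ends that ran past the chromosome length of the headers, 3, 3, 2 and 3 in the 4 lists, were set to that length.

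Chromosome lengths came from the headers. The genome was 139.7 Mb without Uextra, a set of unplaced sequence with 0 regions in any list. Classes were long arms (2L, 2R, 3L and 3R), X, chromosome 4, mapped heterochromatin (2LHet, 2RHet, 3LHet, 3RHet and XHet), Y (YHet) and unplaced (U). Coverage is the percent of bases inside regions, and relative coverage divides it by that of the genome in the same list; values are mean ± SD over 3 replicates. The proximal part of an arm was its 2 Mb at the centromere side, a limit set after the data had been seen, with 1 and 3 Mb as alternatives.

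Regions were called shared when they overlapped by at least 1 bp. Chance overlap came from 1000 circular shifts within each chromosome, with one-sided permutation tests and Benjamini-Hochberg adjustment over the 3 pairs. Median scores of the classes were compared with the long arms by two-sided permutation tests with 100000 resamples, adjusted over the 5 other classes at a threshold of 0.05. An exact sign-flip permutation test was used for relative coverage. Pearson and Spearman correlations of scores were computed across overlapping regions. The overlap code was tested on simulated lists of 3132 regions placed at random: 1 of 20 null runs gave p under 0.05, and in 5 runs with 60% planted overlap the share found differed from that expected by at most 0.946 percentage points. The median test gave p under 0.05 in 1 of 40 null runs and in 10 of 10 runs with scores shifted by 0.3. These runs did not cover regions clustered as in the real lists. Nor did they cover differences as small as those of X (0.064) and chromosome 4 (0.062) in the combined list.

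Named regions were fixed by rule before the data were examined: the 10 strongest combined regions found in all 3 replicate lists, and the 3 strongest of each class found in all 3. Position relative to genes and the 12 gene lists fixed at that time were not run, because the gene table at hand follows release 6 and the regions release 5. Alternatives covered stricter score limits, overlap rules, merging of close regions, subsets of chromosomes, placement of chance regions and leaving out each replicate. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Without read totals the precision of single regions cannot be stated, and errors of coverage and region numbers are the spread between 3 replicates. The 95% intervals of the closing section cover counting error over regions only.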

Results

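HP2 (Su(var)2-HP2) is a chromosomal protein that binds HP1a, the core protein of fly heterochromatin. Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out with the antibody Ab2-90 on wild-type Oregon-R embryos aged 14 to 16 h. The series holds 3 HP2 immunoprecipitation libraries and 3 input libraries of the same embryos. Each immunoprecipitation library came with 1 list of enriched regions called against its own input, and 1 further list covers the replicate set as a whole (the combined list). Read totals were not given in the sources used here, so the depth of each library is unknown and no counting interval is attached to any region. The labels do not say whether the replicates came from separate embryo collections, so the spread between them may be technical.

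The lists contained 2488, 3132 and 3190 regions in replicates 1, 2 and 3, a mean of 2937 ± 390 (SD, n = 3). HP2 regions covered 6.80 Mb in replicate 1, 13.03 Mb in replicate 2 and 11.9 Mb in replicate 3. This was 7.57% ± 2.38 (SD, n = 3) of the 139.7 Mb of sequence considered. Replicate 1 therefore covered a smaller part of the genome than either other replicate. Median region lengths were close, at 1923, 2055 and 2018 bp. Long regions differed more: 63 regions of replicate 1 exceeded 10 kb, against 254 in replicate 2 and 220 in replicate 3. The combined list held 5179 regions covering 17.5 Mb, or 12.5% of the sequence.

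The first question was where along the chromosomes HP2 lies, since HP1a is known from pericentric heterochromatin and from the small chromosome 4. Chromosome 4 was the class most densely covered, with 54.1% ± 15.2 (SD, n = 3) of its bases in HP2 regions. Mapped heterochromatin, the assembled pericentric scaffolds of chromosomes 2, 3 and X, followed with 41.03% ± 14.7 (SD, n = 3). Within this class the scaffolds of chromosomes 2 and 3 were covered over 33.9% to 52.4% on average, and XHet over 3.47% ± 2.12 (SD, n = 3). The long autosomal arms 2L, 2R, 3L and 3R were covered over 4.45% ± 1.30 (SD, n = 3), and the X over 2.10% ± 1.03 (SD, n = 3). Single arms differed, from 7.54% ± 1.62 on 2R to 1.46% ± 0.66 on 3R (SD, n = 3 each), and 3R lay below X in each replicate. Unplaced scaffolds, which hold much repeated sequence, were covered over 13.8% ± 3.95 and the Y scaffold over 8.13% ± 2.56 (SD, n = 3 each).

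**Figure D1:**
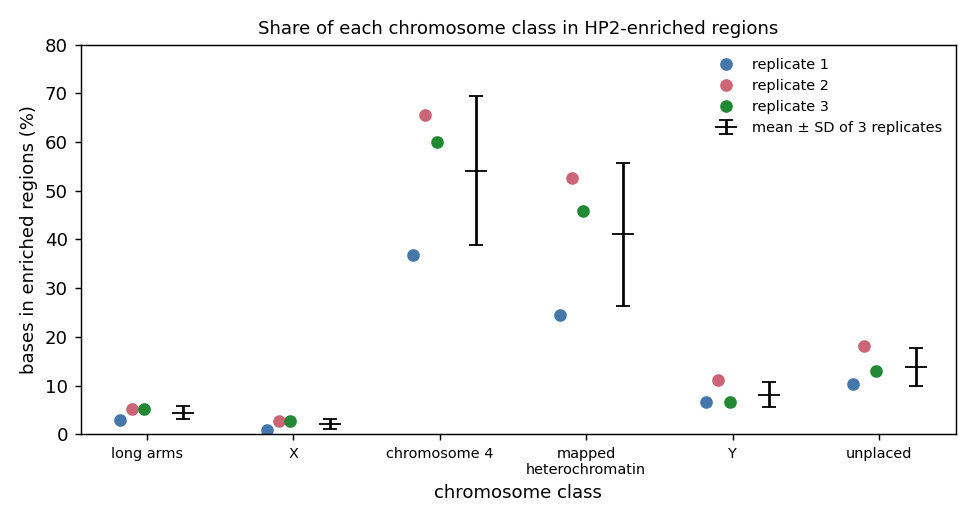
Share of the bases of each chromosome class (horizontal axis) that lie in HP2-enriched regions, in percent (vertical axis); coloured points are the 3 replicate lists and black bars the mean ± SD. Chromosome 4 and mapped heterochromatin stand above the long arms and X in each replicate, and replicate 1 has the lowest value in both.

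Because the lists differ in total coverage, each class was also divided by the coverage of the whole genome in the same list. Chromosome 4 was covered 7.21 ± 0.31 times as densely as the genome and mapped heterochromatin 5.36 ± 0.31 times (SD, n = 3). Unplaced scaffolds reached 1.86 ± 0.30 times, the long arms 0.591 ± 0.033 times and X 0.264 ± 0.069 times (SD, n = 3). The Y scaffold lay at 1.37, 1.19 and 0.779 times in replicates 1, 2 and 3, on both sides of the genome value, and fell from 1.11 to 0.984 on average without replicate 1. For the other classes, the 3 replicates lay on the same side of the genome value. With 3 replicates an exact sign-flip permutation test (two-sided) cannot go below p = 0.25, so the values per replicate are the result. The value for X moved with the choice of list: it was 0.420 in the combined list and 0.150 for combined regions found in all 3 replicate lists. Adding the length of the further unplaced sequence Uextra, which holds no region in any list, took the unplaced value to 0.578. Counting regions per Mb in place of bases gave 4.34 for chromosome 4 and 4.57 for mapped heterochromatin, so the order of these classes turned.

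Along the arms, HP2 regions were concentrated at the centromere-side end of the assembled 2R, 3L and 2L sequences, and little at that of 3R and X. The Het scaffolds are separate from these arm sequences. Among them, 3RHet was covered over 33.9% ± 13.7 and XHet over 3.47% ± 2.12 (SD, n = 3 each). Low coverage of the proximal 3R sequence therefore does not mean that the pericentric sequence of that arm lacks HP2. XHet spans only 0.204 Mb, held 1, 7 and 5 regions in replicates 1, 2 and 3, and was covered over 13.6% in the combined list. It is too short to settle the same question for X. The proximal 2 Mb of 2R was covered over 61.9% ± 10.6, that of 3L over 51.0% ± 14.3 and that of 2L over 31.0% ± 8.66 (SD, n = 3 each). On 3R the same interval was covered over 4.39% ± 2.06, and on X over 2.92% ± 0.93 (SD, n = 3 each). Beyond 2 Mb, coverage ranged from 1.23% ± 0.55 on 3R to 2.01% ± 1.04 on X (SD, n = 3 each). Proximal coverage exceeded distal coverage in each replicate on all 5 arms, by 28.4 to 45.9 times on 2R, 31.6 to 50.6 times on 3L and 17.0 to 23.8 times on 2L. The factor was 3.31 to 3.89 on 3R and 1.19 to 2.32 on X. The 2 Mb limit was set after the profile had been seen, and with 1 Mb the mean factor was 33.5 on 2L, 19.3 on 2R and 19.9 on 3L. At 2 Mb the combined list gave lower factors, at 10.97 on 2L, 16.2 on 2R and 20.1 on 3L.

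**Figure D2:**
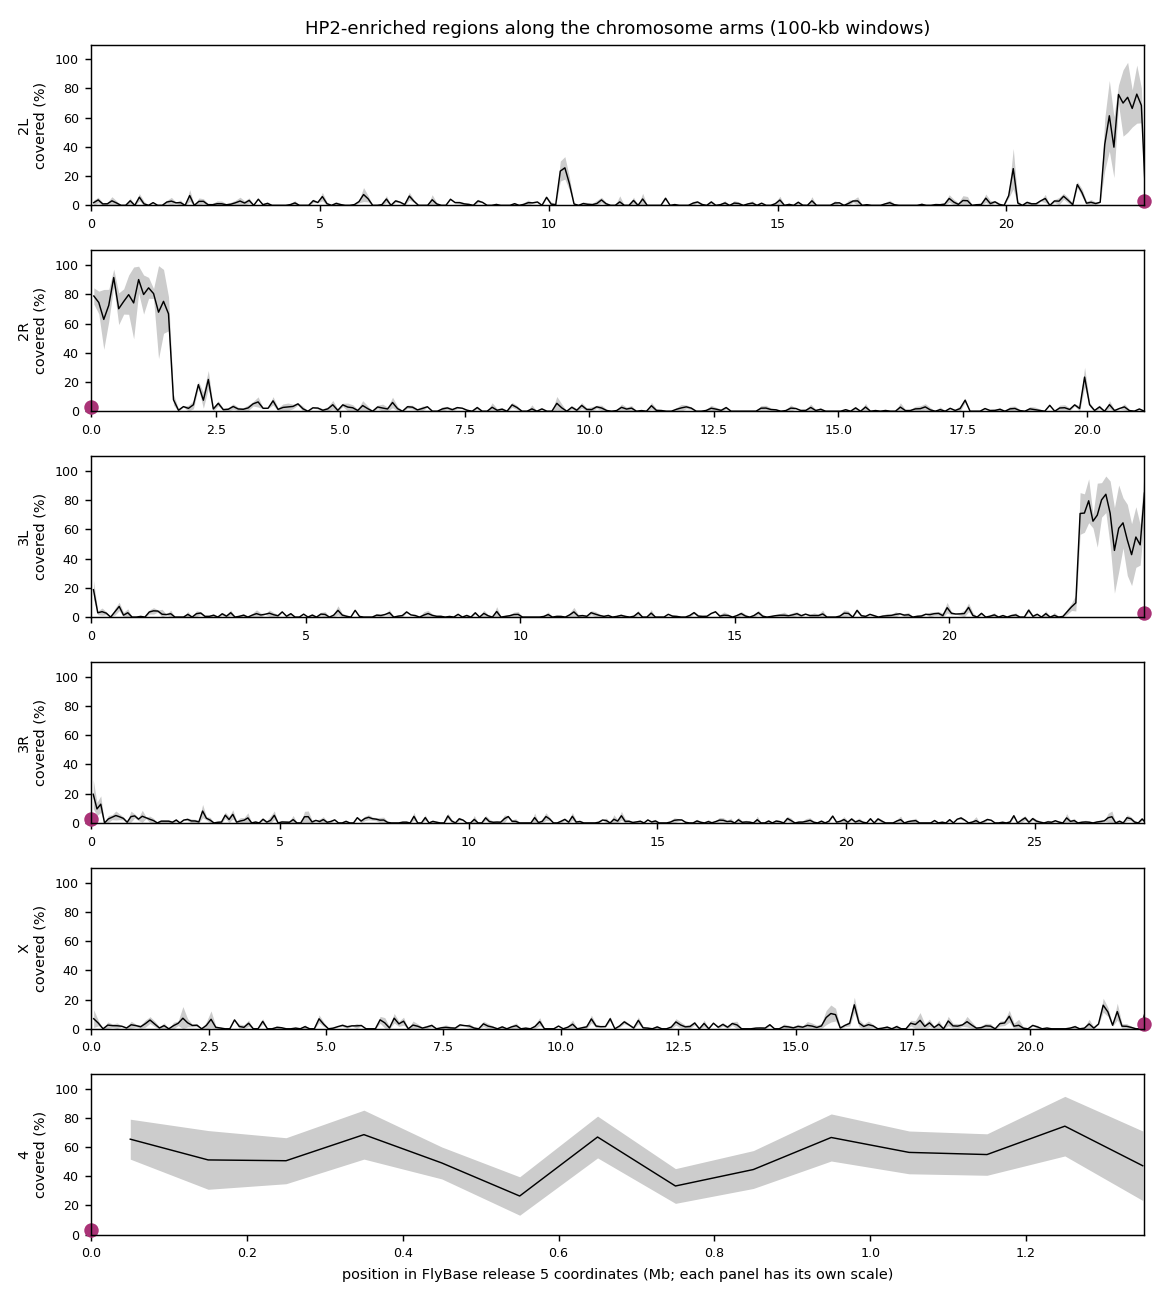
Percent of each 100-kb window in HP2-enriched regions (vertical axis) against position in Mb (horizontal axis, FlyBase release 5) on the 5 large arms and chromosome 4; the line is the mean of 3 replicates, the grey band ± SD and the purple dot the centromere side. The proximal 2 Mb of 2R, 3L and 2L are covered over 61.9%, 51.0% and 31.0% on average, and chromosome 4 over 54.1%.

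The proximal arms, chromosome 4 and mapped heterochromatin together held 70.4% ± 1.10 (SD, n = 3) of the bases in HP2 regions, in 14.5% of the sequence. The longest region of the combined list lay on 2R from 375006 to 485926, over 110.9 kb. In replicates 2 and 3 it was 1 region each, and in replicate 1 it was split into 10 regions that covered 92.9% of it. Regions longer than 10 kb were rare on the distal arms: 0 in replicate 1, 2 in replicate 2 and 1 in replicate 3. In contrast, distal regions had a median length of 1742, 1865 and 1849 bp in the 3 lists.

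The second question was how far the replicates share their regions. HP2 regions of replicates 2 and 3 overlapped most, with 73.0% of replicate 2 regions found in replicate 3 and 78.6% the other way. Of the replicate 1 regions, 78.5% were found in replicate 2 and 75.04% in replicate 3. Only 42.4% of replicate 2 regions and 42.2% of replicate 3 regions were found in replicate 1. Circular shifts of the regions along each chromosome gave 21.7% to 36.3% on average. In each of the 3 pairs no shift out of 1000 reached the observed share in either direction (one-sided permutation test, adjusted p = 0.001, the smallest the shifts can give). In covered bases, the Jaccard index was 0.691 for replicates 2 and 3, 0.393 for replicates 1 and 3 and 0.382 for replicates 1 and 2. Averaged over the 6 directions the share was 65.0%, and it was 37.3% when a region had to share at least 50% with its partner both ways. Under that rule replicates 2 and 3 shared 61.3% and 60.1%, and the 4 directions with replicate 1 gave 21.5% to 30.2%.

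**Figure D3:**
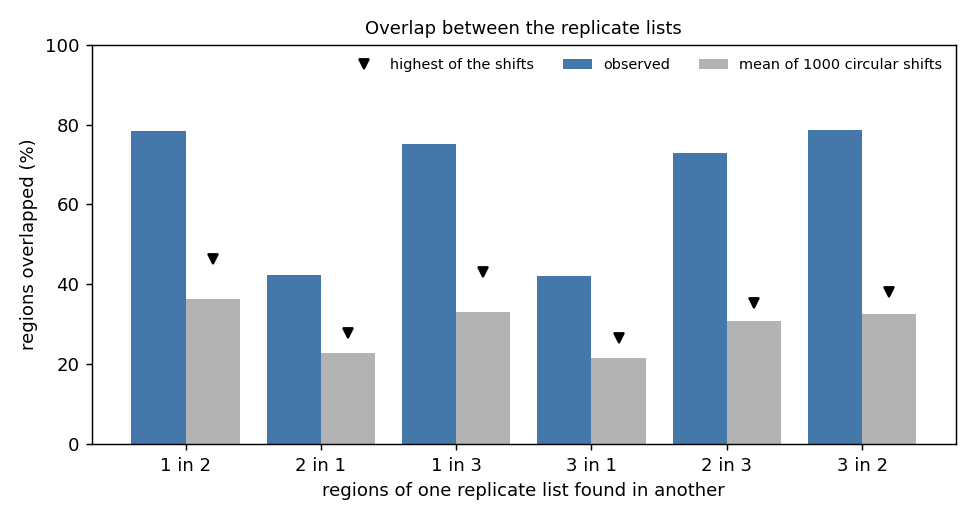
Percent of the regions of one replicate list that overlap a region of another (vertical axis) for the 6 ordered pairs (horizontal axis); blue bars are observed, grey bars the mean of 1000 circular shifts and triangles the highest shift. Each observed share lies above the highest shift, and replicates 2 and 3 are found least in replicate 1, at 42.4% and 42.2%.

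Sharing differed along the chromosomes. Proximal regions of replicate 1 were found in replicate 2 in 92.9% of cases and those on chromosome 4 in 99.3%. The other way, the shares were 61.9% and 45.7%. Shifted within these parts alone, a choice made after seeing the data, the mean over the 6 directions was 80.8% against 57.9% for the shifts on the proximal arms (one-sided permutation test, adjusted p up to 0.0060). On chromosome 4 it was 77.1% against 73.4% (one-sided permutation test, adjusted p up to 0.997), and in mapped heterochromatin 74.7% against 61.7% (one-sided permutation test, adjusted p up to 0.13), so overlap above chance was not shown for each pair there. For distal regions the figures were 64.0% for replicate 1 in replicate 2 and 70.0% for replicate 2 in replicate 3. Distal regions of replicates 2 and 3 were found in replicate 1 in 28.1% and 25.02% of cases. With distal regions alone the mean over the 6 directions was 52.2%, against 2.93% for the shifts. Unlike those of the other parts, these shifts ran over the whole arm, including the proximal 2 Mb emptied of regions, which lowers the chance value.

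Of the 5179 combined regions, 1089 (21.0%) were found in all 3 replicate lists, 1179 in 2 lists, 1176 in 1 list and 1735 (33.5%) in none. Shifted positions, drawn anew for each replicate list, gave 6.63% in all 3, so sharing among the replicate lists is not kept in that value. It is a reference value only, because the combined list covers the same replicate set and an excess follows from that. The share in all 3 was 40.8% on the proximal arms, 36.1% in mapped heterochromatin, 32.6% on chromosome 4 and 11.4% on the distal arms. Among these parts a shift value was computed for the distal arms only, at 0.035%. Regions in all 3 lists had medians of 8761 bp on the proximal arms and 14407 bp on chromosome 4, against 2228 bp on the distal arms. Long regions meet a 1 bp rule more easily, so the order of the shares does not rank the parts by sharing above chance. Without replicate 1, 39.9% of combined regions were found in both remaining lists. A 50% overlap both ways left 8.73% in all 3. The combined list held 99.9% of replicate 2 regions, 92.0% of replicate 3 regions and 87.7% of replicate 1 regions. Combined regions found in no replicate list were short, with a median of 1203 bp against 5097 bp for those in all 3.

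**Figure D4:**
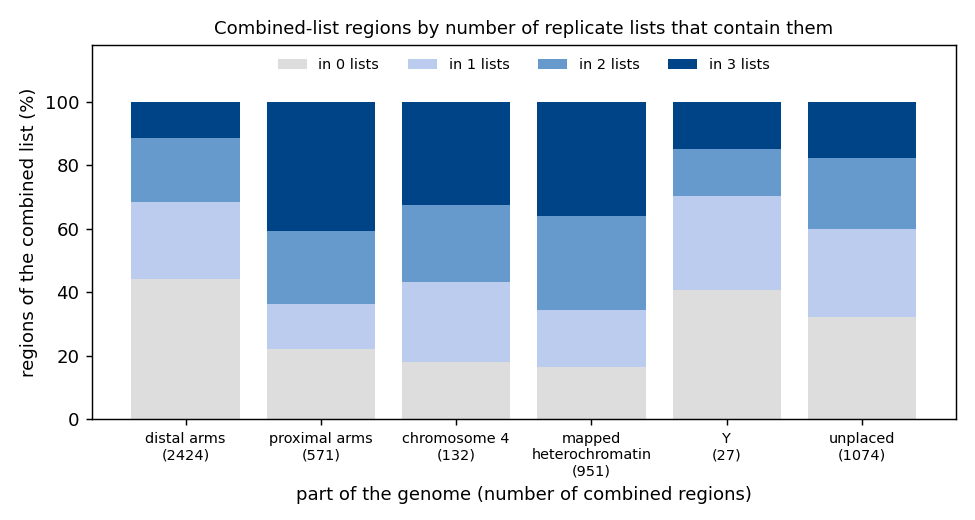
Regions of the combined list (vertical axis, percent) by the number of replicate lists that contain them, for each part of the genome (horizontal axis, number of regions in brackets). Regions found in all 3 lists make up 40.8% on the proximal arms and 11.4% on the distal arms, without allowance for chance overlap, which differs between the parts.

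The third question was whether regions differ in strength between chromosomes. The deposited score per region was read as a log2 value whose zero is not known, so scores are compared within a list. In the combined list, the median score was 0.46 on the long arms, 0.52 on X and on chromosome 4, 0.72 in mapped heterochromatin, 0.90 on unplaced scaffolds and 0.94 on the Y scaffold. Each class differed from the long arms (two-sided permutation test of medians, 100000 resamples, adjusted p = 1e-05 each, the smallest the resamples can give). Regions are not independent replicates, so these tests describe the list. On unplaced scaffolds the median was 1.02 for regions in 0 replicate lists and 0.91 for those in all 3. A higher score there did not go with presence in more lists. In every other part of the genome, regions in all 3 lists had the higher median, as on the distal arms (0.62 against 0.46). Among regions found in all 3 replicate lists, chromosome 4 kept the higher median, at 1.14 against 0.81 (permutation test, adjusted p = 4.5e-04). In that subset mapped heterochromatin (0.85, permutation test, adjusted p = 0.24), X (0.69, permutation test, adjusted p = 0.11) and the 4 Y regions (1.26, permutation test, adjusted p = 0.11) were not separated from the long arms. There the lead of unplaced scaffolds was 0.10 (permutation test, adjusted p = 0.017), against 0.44 in the whole combined list. In the replicate 1 list alone, neither X (permutation test, adjusted p = 0.12) nor chromosome 4 (permutation test, adjusted p = 0.093) was separated from the long arms. Mapped heterochromatin led them by 0.030 in that list (permutation test, adjusted p = 0.0088), against 0.26 in the combined list.

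The 10 strongest combined regions found in all 3 replicate lists were pericentric or unplaced, and 8 of them were still found in all 3 with a 50% overlap both ways. The first was on the 2RHet scaffold from 1776970 to 1780994, with a score of 3.07. The next 2 were on the unplaced sequence U, from 9339780 to 9342948 (score 2.87) and from 4667056 to 4670254 (score 2.75). On 2R, the regions from 110522 to 116046 and from 127468 to 142960 scored 2.60 and 2.49, and the region from 1234828 to 1256066 scored 2.41. On 2L, the region from 22259726 to 22266740 scored 2.53. On 3L, the regions from 24012832 to 24017014 and from 23109884 to 23120062 scored 2.49 and 2.43, and on the 3LHet scaffold the region from 2188812 to 2203216 scored 2.40. The 6 regions on 2L, 2R and 3L lay between 0.11 and 1.43 Mb from the centromere-side end of their arm. On chromosome 4 the leading regions ran from 12 to 6716, from 969612 to 987028 and from 193028 to 247502, with scores of 1.82, 1.79 and 1.70. The strongest X region, from 15826590 to 15830238 with a score of 1.93, lay 6.59 Mb from the centromere side; it was followed by those from 21500186 to 21504286 (score 1.51) and from 15653722 to 15656312 (score 1.46). The strongest Y regions, on YHet from 297072 to 306850, from 340572 to 345100 and from 318842 to 321878, scored 1.53, 1.39 and 1.13. The third regions of mapped heterochromatin (3LHet, 2208380 to 2216058) and of U (5131510 to 5135304) scored 2.18 and 2.39.

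Scores of overlapping regions agreed more between replicates 2 and 3 than with replicate 1. Across regions, Spearman's rho was 0.85 (Pearson's r 0.88) over 2286 overlapping pairs for replicates 2 and 3. It was 0.52 (r 0.57) over 1867 pairs for replicates 1 and 3, and 0.49 (r 0.56) over 1953 pairs for replicates 1 and 2. These are correlations across regions, which are not independent replicates, so no p is given. Each region of the lower-numbered list was paired with the region sharing most bases, so several regions could have the same partner. For replicates 1 and 2, the 1953 regions of replicate 1 overlapped 1329 regions of replicate 2. Requiring a 50% overlap both ways raised rho to 0.71 for replicates 1 and 2 and to 0.70 for replicates 1 and 3. For replicates 2 and 3 it was then 0.89.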

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

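Alternatives with the proximal limit, Uextra, distal arms or dense parts alone, short regions left out long arms without their proximal part and overlap rules for the named regions were chosen after seeing the data, as was leaving out a replicate for region numbers and score agreement. Of 13 alternatives for overlap between replicates, 11 stayed above chance with a range of 37.3% to 80.8%. Those that left out a replicate repeat single pairs already given and are no further check. On chromosome 4 alone (77.1%) and mapped heterochromatin alone (74.7%) at least 1 pair missed the threshold, and on chromosome 4 replicate 2 in 1 (45.7%), 3 in 1 (54.5%) and 2 in 3 (75.2%) fell below the shifts. Combined regions in all 3 lists ranged from 8.73% to 36.5%, and without replicate 1 the share in both remaining lists was 39.9%. The mean number of regions was 1468 in the upper part of each list by score and 1525 on the main arms, by construction. Relative coverage kept its side of the genome value for the long arms, X, chromosome 4 and mapped heterochromatin in all alternatives. Leaving out a replicate could not change that side, because each replicate lay on it. Counting regions per Mb gave X 0.497, chromosome 4 4.34, mapped heterochromatin 4.57, Y 1.78 and unplaced 2.60. The upper part by score gave long arms 0.557, X 0.146, chromosome 4 8.16, mapped heterochromatin 5.76 and Y 1.42. The combined list gave X 0.420, chromosome 4 5.63, mapped heterochromatin 4.97, Y 1.51 and unplaced 2.26. Combined regions in all 3 lists gave X 0.150, chromosome 4 8.25, mapped heterochromatin 6.27, unplaced 1.47 and Y 0.880, below the genome. With Uextra in the length, long arms reached 0.714, chromosome 4 8.71 and mapped heterochromatin 6.47, and unplaced fell below the genome at 0.578, because length without regions was added. Proximal coverage stayed above distal coverage throughout, which leaving out a replicate could not change, since it held in each. The factor with 1 Mb was 33.5 on 2L, 19.3 on 2R, 19.9 on 3L, 4.77 on 3R and 3.01 on X. With 3 Mb it was 15.1 on 2L, 27.3 on 3L and 2.96 on 3R. In the combined list it was 10.97 on 2L, 16.2 on 2R, 20.1 on 3L and 2.67 on 3R. For score differences from the long arms, 28 of 35 alternatives kept the call. In replicate 1 alone X (0.037) and chromosome 4 (0.040) missed the threshold. Among regions in all 3 lists mapped heterochromatin (0.041) and Y (0.46, with 4 regions) missed it, and X was at -0.12, also short of the threshold. With length in place of score, Y differed by 72 bp and X by -74 bp, neither passing. Among regions in all 3 lists the long-arm reference held a larger proximal part. Beyond that, the cause was not tested for these changes. Leaving out a replicate left 1 pair of lists, so Spearman's rho was then that of each pair given above, from 0.49 to 0.85. It is no further check, and the highest value was that without replicate 1.

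No paired analysis was possible because the input libraries, which share replicate numbers with the immunoprecipitations, have no values of their own here. Not run were a threshold by p or q (the lists carry none) and lengths without runs of N (no genome sequence of this release was at hand). The largest coordinate as length (the headers give lengths) and the alternatives for gene positions and gene lists were not run either. The unknown depth leaves open how many weak regions each list missed.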

Other observations

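The windows and patterns described here were chosen after the data had been seen. Away from the centromeres, mean coverage was higher in a few windows of otherwise sparsely covered arms, though 0 windows exceeded 20% in all 3 replicates. Over 1089 distal windows of 100 kb the median of the replicate means was 1.05%, and 314 windows held no region in any replicate. On 2L, the window from 10300001 to 10400000 was covered over 25.7% ± 7.69, with 16.8% in replicate 1, and its neighbour from 10200001 to 10300000 over 23.5% ± 6.85 (SD, n = 3 each). A second 2L window, from 20100001 to 20200000, was covered over 25.1% ± 13.9, with 9.72% in replicate 1 and 36.6% in replicate 2. On 2R, the window from 19900001 to 20000000 reached 23.3% ± 6.73, with 15.7% in replicate 1, and on X that from 16200001 to 16300000 reached 16.4% ± 5.21 (SD, n = 3 each). On 2R the windows from 2100001 to 2200000 and from 2300001 to 2400000, just outside the proximal 2 Mb, were covered over 18.2% ± 2.24 and 21.7% ± 6.13 (SD, n = 3 each).

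The chromosome ends away from the centromere differed. The first 100 kb of 3L was covered over 11.6%, 23.5% and 21.2% in replicates 1, 2 and 3. The same interval of X was covered over 1.61%, 13.5% and 5.59%. On 2L, 2R and 3R the terminal 100 kb stayed at or below 3.53% in each replicate. The terminal 100 kb of chromosome 4 was covered most, over 32.7%, 74.5% and 65.9% in replicates 1, 2 and 3. Chromosome 4 as a whole was covered over 36.9%, 65.5% and 60.1%, so its end was near the level of the chromosome, and below it in replicate 1.

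The tests of repeated sequence on unplaced scaffolds and of a single library behind the X density were chosen after the result was seen; the other 4 were written down before. The replicate 1 list held fewer of its regions on X and 3R, 8.96% against 17.6% and 18.9% in replicates 2 and 3. Replicates 2 and 3 were then restricted to their strongest 2488 regions, as many as replicate 1 holds. The gap fell from 8.63 to 4.46 percentage points (95% interval 2.71 to 6.21, treating regions as independent) for replicate 2. For replicate 3 it fell from 9.97 to 6.71. Both gaps passed the 4 points set beforehand against list length alone, though the interval of replicate 2 reached below that limit. The share counts regions, and replicate 1 held 565 regions on the proximal arms, against 446 and 492 in the longer lists. Splitting of dense parts into more regions lowers the share on X and 3R at any list length, so the test does not decide on list length alone. Weaker regions missed in replicate 1 stay open: among 746 distal replicate 3 regions shared with replicate 2, those also present in replicate 1 outscored the absent ones with a probability of 0.698. That value would be 0.5 with no relation to score. No biological explanation was tested, since the replicates form 1 group.

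Short regions were over-represented among the highest combined scores: 120 of the top 258 regions (5% of the list) were below 1301 bp, the shortest length in any replicate list, against 25.9% of the whole list. Of these 120, 61.7% lay on the unplaced sequence U, against 39.1% of the longer top regions and 20.7% of all combined regions. Repeated sequence placed on unplaced scaffolds stays open as a candidate explanation, and part of the excess on U is shared by top regions of any length. Ratios of few reads cannot be told apart from the length limit: longer top regions were found in a replicate list more often by 69.5 percentage points, past the 20 points set beforehand. The gap was 63.5 points over all scores, seen afterwards, so the test does not separate them. Read counts per region would be needed to decide. No biological explanation was tested.

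Beyond 2 Mb from the centromere-side end, X held 28.2 combined regions per Mb, against 18.8 to 26.3 on the autosomal arms. Beyond 1 Mb, X (27.96) and 2R (27.95) were nearly level. Support in the replicate lists was low on X and on the autosomal arms alike. Of distal X regions, 33.0% were found in at least 2 replicate lists and 43.6% in none. For distal autosomal regions the shares were 31.2% and 44.5%. The difference in support of 1.82 percentage points (95% interval -2.56 to 6.20, treating regions as independent) argues against lower support on X, for which at least 10 points fewer were predicted. X held the most distal regions per Mb in 2 of the 3 replicate lists, while in replicate 1 the value was 4.55 on X and 5.48 on 2R. The lead over 2R had a 95% counting interval above 0 in 0 of 3 lists (-0.076 to 4.21 per Mb in replicate 2 and -0.67 to 3.89 in replicate 3). Such intervals measure counting error and cannot tell whether 1 library made the difference, so the test does not decide that. The order also moved with the limit, since X led in 0 of 3 lists at 1 Mb and in 3 of 3 at 3 Mb. No biological explanation was tested.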
